A study of Homo sapiens with 18 samples.

How the data were processed

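RNA was measured by sequencing in 18 libraries of HAP1 cells: WT, C12orf49 KO and SREBF2 KO, each as control and after 4 h without serum, with 3 biological replicates per group. Per the labels' protocols, cells were kept in DMEM with 10 mM glucose, 1 mM glutamine and 10% FBS and cultured for 48 h before the treatment ended in control or serum-free conditions. Per the same protocols, poly(A) RNA from 1000 ng was made into directional libraries with 8 cycles of amplification. The deposited values are whole-number counts of reads per gene, made with STAR on hg38 per the submitters' processing notes, in 1 table per library and in 1 merged table with gene symbols. The STAR version and the annotation are not given in the sources used here.

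Each table per library holds counts for unstranded reading and for each strand, and the strand of the directional kit was used. It held 93.5 to 94.0% of the reads assigned to either strand, or 18973748 to 33211605 reads per library out of 25378898 to 45601280. The merged table equals that strand's column for 37919 of 37919 genes in each library, and 419 of its 38344 entries hold no value. The summary lines at the top of each table stayed out of library sizes: 15.4 to 21.2% of reads were unmapped, 2.29 to 3.03% mapped to several places, 3.08 to 4.74% fell in no gene and 2.89 to 3.12% were ambiguous. Mitochondrial genes took 0.431 to 1.08% of assigned reads and the 10 most abundant genes 4.08 to 4.90%. Between 22856 and 28116 genes had reads in a library. WT control 1 (28116 genes, 4.70% in no gene) and SREBF2 KO starved 1 (27058 genes, 4.74% in no gene) stood apart from the rest in these measures. In the SREBF2 KO starved libraries 18.3, 20.4 and 21.2% of reads were unmapped, against 15.8 to 16.2% in SREBF2 KO control. This difference goes with the treatment in that genotype, so its part in the response of SREBF2 KO cannot be told apart. Of 58037 genes, 45 duplicate entries of the pseudoautosomal regions (4 reads in all) were left out.

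Genes were kept by the edgeR function filterByExpr, which left 17692 of 57992. Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3) by a robust quasi-likelihood model with 1 mean for each of the 6 groups (12 residual degrees of freedom). Each of 12 contrasts was tested two-sided, and p was adjusted over all tested genes by the method of Benjamini and Hochberg with a threshold of 0.05. The contrasts were the response to 4 h without serum in each genotype, the genotypes against each other at each treatment, and the 3 differences between responses. The SE of a log2 fold change comes from the same model. Log2 fold changes were also tested against a fold of 1.5. Replicates of a group had r of at least 0.992 between log2 CPM values (prior count 2). Their counts varied by 2.09 to 8.75 times the Poisson variance (chi-square per degree of freedom), with a common biological coefficient of variation of 4.42%. The median log2 fold change over all genes lay within 0.0201 of 0 in each contrast.

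24 gene lists (401 genes, 357 of them tested) were written from textbook knowledge. Lists with at least 4 tested genes were tested in each contrast with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and p was adjusted over the lists within a contrast. Camera compares a list with all other genes, so a list whose members changed with most other genes can miss its threshold. Calls were compared with camera at an estimated correlation and with fry.

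The genes named are C12orf49 and SREBF2, and in each contrast the 6 highest and 6 lowest called log2 fold changes. The latter were taken among genes at a mean log2 CPM of at least 1 with a gene symbol and, for contrasts of 2 groups, no overlap between the groups. Up to 4 called members with the smallest p were named from each list that passed camera and up to 2 from each other list. Members of the lists on cholesterol synthesis, sterol uptake and transport, SREBP machinery and fatty acid synthesis could be named in any contrast. Not all of these genes are printed, and some items are not reported here. The tests, the lists, this rule and the alternatives were fixed before the data were examined, except where the text says that a choice was made after seeing the data.

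The fit was tested on simulated counts with 200 changed genes, 50 for each of the folds 1.25, 1.5, 2 and 4. For the response of WT it called 64%, 80%, 96% and 100% of them, with 5.56% false calls, over 17015 genes. For C12orf49 KO against WT at control it called 64%, 80%, 100% and 100%, with 5.49% false calls, over 17022 genes. For the difference between the responses of C12orf49 KO and WT it called 40%, 72%, 92% and 100%, with 5.00% false calls, over 17043 genes. In simulated lists for the response of WT, camera called 3 of 3 lists shifted 1.3-fold and 0 of 19 lists without shifted members, over 17692 genes. These counts were drawn independently for each gene, so they cannot show how camera at the preset correlation behaves with correlated members. In the data the estimated correlation of ATF4 targets in the response of WT was 0.358.

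After the data were seen, genes were ordered by position (11708 genes with a mean log2 CPM above 2). Segments were taken where the running median over 21 genes of the log2 fold change against WT at control passed 0.35 in size. No segment was found in any of 100 shuffles of the gene positions for either knockout, and a segment of 100 genes planted in the values was found for each.

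The alternatives were RLE size factors, library size alone, DESeq2 1.42.0, no filter on low counts, a stricter filter (CPM of at least 1 in at least 3 libraries), the unstranded counts, only the libraries compared, the replicate number in the model, and leaving out each library in turn. Added after the data were seen were the data without WT control 1 and SREBF2 KO starved 1, and the data without the genes of the 2 chromosome segments and 3 other genes.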

Results

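RNA was sequenced from HAP1 cells, a near-haploid human line, of 3 genotypes: wild type (WT), C12orf49 KO and SREBF2 KO. SREBF2 encodes the transcription factor SREBP-2, which acts on genes of sterol synthesis and uptake, and C12orf49 (also named SPRING1) encodes a membrane protein of the SREBP pathway. Each genotype was sampled as control and after 4 h without serum, in 3 biological replicates per group. The comparisons address how the response of lipid genes to serum withdrawal differs between these genotypes. Changes are log2 fold changes ± SE from edgeR (n = 3 libraries per group, hg38 annotation), and levels are CPM (read counts scaled to library size, with TMM factors) as mean ± SD (n = 3). Genes are said to rise, fall, or lie higher or lower at an adjusted p under 0.05. Counts in a list are out of its measured genes. Counts adjusted over the list alone are given only where they differed. SREBP machinery holds C12orf49 and SREBF2, so its tests include the edited genes. A camera result without a second p also held with an estimated correlation. The labels name 1 line per knockout, and they do not say whether control cultures received fresh medium at the start of the 4 h, so the responses compare serum-deprived cultures with controls whose medium renewal is not stated.

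SREBF2 itself (ENSG00000198911.11, chromosome 22, 41833079 to 41907308) was lower in SREBF2 KO than in WT. Its mRNA stood at 302 ± 1.55 CPM in WT control and 202 ± 3.05 CPM in SREBF2 KO control, a log2 fold change of -0.58 ± 0.034 (edgeR adjusted p = 2.64e-17). Without serum SREBF2 rose in WT to 439 ± 5.71 CPM (0.54 ± 0.034) and in C12orf49 KO from 291 ± 7.10 to 432 ± 2.59 CPM (0.57 ± 0.034). In SREBF2 KO it reached 220.3 ± 8.33 CPM (0.13 ± 0.035), and this response was smaller than that of WT by -0.41 ± 0.048. C12orf49 mRNA (ENSG00000111412.5, chromosome 12, 116710185 to 116738070) was 79.8 ± 2.19 CPM in WT control and 66.8 ± 3.03 CPM in C12orf49 KO control (-0.25 ± 0.048, edgeR adjusted p = 4.35e-05). It rose without serum in WT (0.21 ± 0.047) and in C12orf49 KO (0.37 ± 0.047), and fell in SREBF2 KO (-0.14 ± 0.047), a call that ended without SREBF2 KO control 2 (adjusted p = 0.172). A transcript with a small insertion or deletion can keep its level, so neither mRNA level checks the knockout labels.

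In WT cells, 4 h without serum raised most enzymes of cholesterol synthesis. HMGCS1 (ENSG00000112972.14, chromosome 5, 43289395 to 43313512), whose product makes HMG-CoA, rose 2.80-fold, from 139 ± 5.77 to 390.0 ± 12 CPM (log2 1.49 ± 0.04, edgeR adjusted p = 2.57e-28). The later steps MSMO1 (1.36 ± 0.053), IDI1 (1.13 ± 0.042) and LSS (1.07 ± 0.036) rose as well, and so did INSIG1, which holds the SREBP escort protein SCAP in the endoplasmic reticulum (1.5 ± 0.051). In the whole cholesterol list 18 of 20 genes rose and 1 fell (median log2 fold change 0.94, camera adjusted p = 1.96e-22); the gene that fell was PMVK (-0.19 ± 0.056). Among sterol uptake and transport genes 7 of 11 genes rose and 1 fell (median log2 fold change 0.56, camera adjusted p = 2.81e-04). The sterol carrier STARD4 rose 2.53-fold (1.34 ± 0.059) and the lysosomal exporter NPC1 1.51-fold (0.59 ± 0.057). MYLIP, which encodes a ubiquitin ligase, fell 1.99-fold (-0.99 ± 0.094).

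Part of the fatty acid synthesis genes rose in WT. In that list 12 of 21 genes rose and 3 fell (median log2 fold change 0.21, camera adjusted p = 2.81e-04, adjusted p = 0.0997 with an estimated correlation). FADS1 (0.80 ± 0.042), SCD (0.61 ± 0.038) and ACLY (0.59 ± 0.037) rose, which encode a desaturase of polyunsaturated chains, stearoyl-CoA desaturase and ATP citrate lyase. In glycerolipid and phospholipid synthesis, 6 genes rose and 8 fell, with PNPLA3 up 3.46-fold and the phosphatidate phosphatase LPIN1 1.73-fold. That list's median (-0.09) and mean (0.09) differed in sign and it did not pass camera (adjusted p = 0.819). Nor did SREBP machinery (5 up, 5 down, adjusted p = 0.559), LXR targets (2 up, 3 down, 0.843) or PPAR targets and fatty acid oxidation (4 up, 1 down, 0.247).

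The ATF4 targets, which serve amino acid synthesis, amino acid transport and the stress response, fell in WT without serum. In this list 0 of 24 genes rose and 22 fell (median log2 fold change -1.09, camera adjusted p = 4.64e-28). Asparagine synthetase, ASNS, fell 3.82-fold (-1.93 ± 0.044), the serine synthesis gene PSAT1 3.06-fold (-1.62 ± 0.043), the amino acid carrier SLC7A5 2.97-fold (-1.57 ± 0.04) and CHAC1, which degrades glutathione, 7.22-fold (-2.85 ± 0.069). G1/S genes fell too: 0 of 17 genes rose and 15 fell, or 1 and 16 adjusted over the list alone (median log2 fold change -0.32, camera adjusted p = 5.40e-11), with MCM5, MCM3 and CDT1, which license replication origins, lower by 1.59-fold, 1.47-fold and 1.61-fold. Of the G2/M genes, 1 of 15 genes rose and 11 fell (median log2 fold change -0.28, camera adjusted p = 7.04e-05, adjusted p = 0.0996 with an estimated correlation), including the mitotic kinases PLK1 (-0.52 ± 0.04) and AURKB (-0.58 ± 0.044). In ribosome biogenesis, 0 of 18 genes rose and 14 fell, or 1 and 15 adjusted over the list alone (median log2 fold change -0.24, camera adjusted p = 2.35e-05, adjusted p = 0.0997 with an estimated correlation). YAP and TAZ targets, which follow cell spreading, gave 1 up and 6 down of 13 (median -0.11, camera adjusted p = 0.00901, adjusted p = 0.108 with an estimated correlation), with AJUBA (-1.02 ± 0.048), CYR61 (-1.19 ± 0.073) and CTGF (-1.39 ± 0.15). For actin and SRF targets, 1 of 14 genes rose and 10 fell (median log2 fold change -0.20, camera adjusted p = 6.51e-04, adjusted p = 0.0996 with an estimated correlation).

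FOXO targets rose in WT without serum: 11 of 18 genes rose and 2 fell (median log2 fold change 0.46, camera adjusted p = 9.81e-05, adjusted p = 0.0657 with an estimated correlation). BCL6, a transcriptional repressor, rose 4.18-fold (2.06 ± 0.081), and TXNIP, which limits glucose uptake, 1.98-fold (0.99 ± 0.061). Among lysosome genes 11 of 20 genes rose and 3 fell, or 12 and 3 adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.00883, adjusted p = 0.0657 with an estimated correlation). Lists that did not pass camera in WT were immediate early genes (adjusted p = 0.30), ERK output genes (0.0648), endoplasmic reticulum chaperones (0.0996), hypoxia and glycolysis (0.975), oxidative phosphorylation (0.0727), interferon-stimulated genes (0.976), epithelial markers (0.646), fibroblast and mesenchymal markers (0.109) and haematopoietic markers (0.612). The median, mean and test differed in sign for hypoxia and glycolysis (-0.01, 0.03, up), interferon-stimulated genes (0.14, -0.27, down) and haematopoietic markers (0.11, -0.87, up). The largest rises among genes at a log2 CPM of at least 1 were RASGRF2 15.8-fold, RBM47 15.5-fold, OLIG3 12.7-fold, ATP8B4 12.1-fold, CAPN6 10.2-fold and DPYSL3 9.35-fold. RASGRF2 encodes a Ras exchange factor, RBM47 an RNA-binding protein, and DPYSL3 a protein of axon growth. The largest falls were MT1E 11.9-fold, LRRC31 9.47-fold, MT2A 8.93-fold, CHAC1 7.22-fold, INHBE 7.14-fold and MT1F 5.88-fold, where MT1E, MT2A and MT1F are metallothioneins of near-identical sequence, so which family members changed is uncertain. In all, 4218 of 17692 tested genes rose and 4055 fell, 437 and 462 of them by at least 2-fold, and 712 passed a test against a fold of 1.5.

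**Figure D1:**
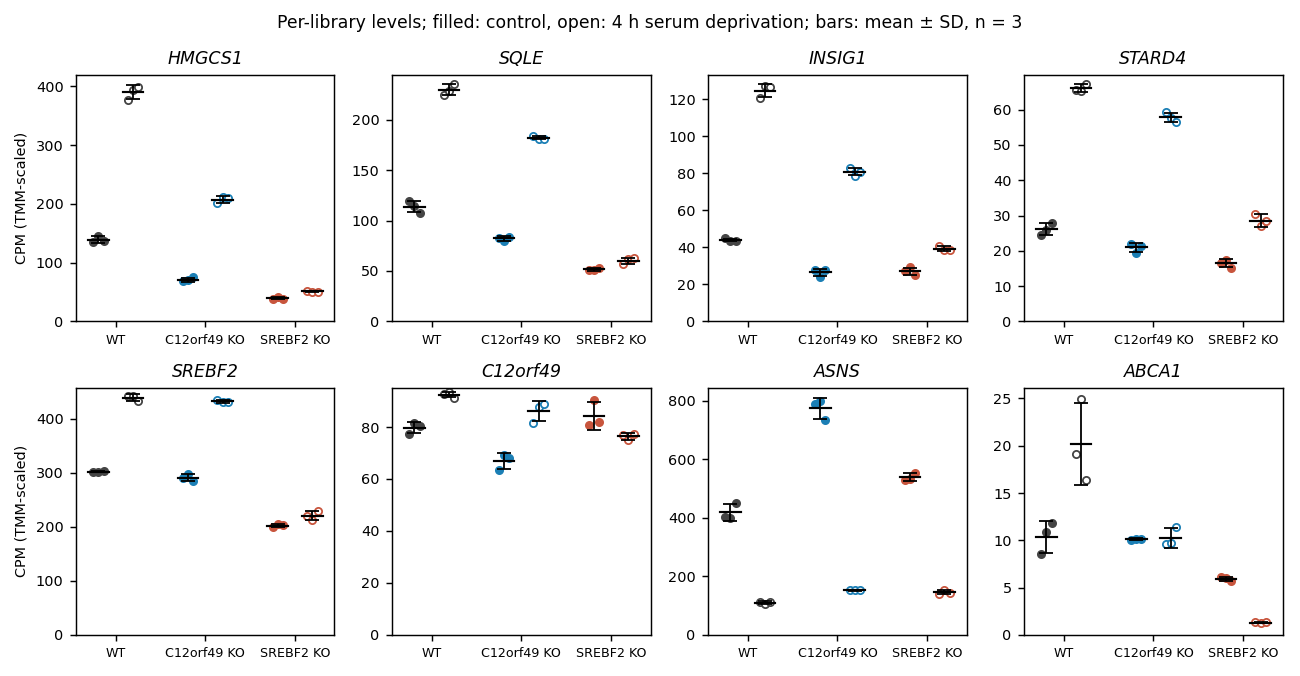
Per-library CPM of 8 genes in the 6 groups, with filled points for control, open points for 4 h without serum, and bars for the mean ± SD (n = 3). HMGCS1 rose from 139 ± 5.77 to 390.0 ± 12 CPM in WT and from 39.3 ± 1.64 to 51.0 ± 1.26 CPM in SREBF2 KO.

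C12orf49 KO cells also raised cholesterol synthesis genes without serum, from lower starting levels. HMGCS1 rose 2.91-fold (1.54 ± 0.042, edgeR adjusted p = 1.06e-28), from 71.2 ± 3.41 to 207 ± 5.82 CPM, and MSMO1 (1.72 ± 0.057), IDI1 (1.42 ± 0.044) and DHCR7 (1.3 ± 0.04) rose with it. In the list, 18 of 20 genes rose and 0 fell, or 18 and 1 adjusted over the list alone (median log2 fold change 1.06, camera adjusted p = 6.96e-17). STARD4 rose 2.75-fold (1.46 ± 0.061) and INSIG1 3.04-fold (1.60 ± 0.055), while MYLIP fell 2.33-fold (-1.22 ± 0.095). Among sterol uptake and transport genes 7 of 11 genes rose and 2 fell (median log2 fold change 0.59, camera adjusted p = 0.0297, adjusted p = 0.0867 with an estimated correlation); without the genes of the chromosome segments described further on, camera gave an adjusted p of 0.109. Fatty acid genes gave 12 up and 5 down of 21, or 13 and 5 adjusted over the list alone (median 0.19, camera adjusted p = 0.00515, adjusted p = 0.220 with an estimated correlation). HACD3 (0.69 ± 0.035), FADS1 (0.71 ± 0.041), ACLY (0.62 ± 0.037) and SLC25A1 (0.63 ± 0.04) rose.

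ATF4 targets fell in C12orf49 KO without serum. In that list 0 of 24 genes rose and 23 fell (median log2 fold change -1.86, camera adjusted p = 4.13e-27). ASNS fell 5.06-fold (-2.34 ± 0.044), PSAT1 4.30-fold (-2.10 ± 0.043) and MTHFD2, of mitochondrial folate metabolism, 2.86-fold (-1.51 ± 0.035). XBP1 and HERPUD1, of the unfolded protein response, fell 2.80-fold and 2.44-fold, while endoplasmic reticulum chaperones as a list did not pass camera (adjusted p = 0.589). Lysosome genes rose: 16 of 20 genes rose and 3 fell (median log2 fold change 0.38, camera adjusted p = 5.80e-05); LAMP1 rose 1.80-fold, NEU1 1.87-fold, and GLA 1.5-fold, which lies in the chromosome X segment described further on. YAP and TAZ targets fell: 0 of 13 genes rose and 11 fell, or 1 and 11 adjusted over the list alone (median log2 fold change -0.40, camera adjusted p = 3.45e-04, adjusted p = 0.0505 with an estimated correlation). Examples were AJUBA (-1.28 ± 0.047), AMOTL2 (-1.3 ± 0.059) and CTGF (-1.43 ± 0.12). Of the G1/S genes, 1 of 17 genes rose and 12 fell (median log2 fold change -0.20, camera adjusted p = 3.45e-04, adjusted p = 0.0867 with an estimated correlation). Of the G2/M genes, 0 of 15 genes rose and 12 fell (median log2 fold change -0.28, camera adjusted p = 5.80e-05, adjusted p = 0.0867 with an estimated correlation). For fibroblast and mesenchymal markers 0 of 8 genes rose and 7 fell, or 1 and 7 adjusted over the list alone (median log2 fold change -0.46, camera adjusted p = 0.00515), including the cadherin CDH2 and the intermediate filament VIM (-0.63 ± 0.042 and -0.53 ± 0.035). For ERK output genes, 2 of 15 genes rose and 8 fell, or 2 and 9 adjusted over the list alone (median log2 fold change -0.33, camera adjusted p = 0.0166, adjusted p = 0.170 with an estimated correlation), with ETV4 6.03-fold lower. The largest rises were ATP8B4 22.9-fold, RASGRF2 17.6-fold, CAPN6 15.8-fold, SYN1 15.5-fold, OLIG3 14.5-fold and COL11A1 11.2-fold (from 5 reads at control, all in 1 library), and the largest falls MT1E 29-fold, LRRC31 25.7-fold, INHBE 21.5-fold, ZNF619 20.2-fold, MT2A 19.1-fold and MYH15 17.9-fold. In all, 4870 genes rose and 5026 fell, 634 and 1179 by at least 2-fold, and 1964 passed the test against a fold of 1.5.

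SREBF2 KO cells raised cholesterol synthesis genes by smaller amounts. HMGCS1 rose 1.3-fold (0.38 ± 0.048, edgeR adjusted p = 1.71e-08), from 39.3 ± 1.64 to 51.0 ± 1.26 CPM. IDI1 rose 1.54-fold (0.62 ± 0.047), FDFT1, which makes squalene, 1.39-fold (0.47 ± 0.042) and LSS 1.36-fold (0.44 ± 0.037). In the list, 15 of 20 genes rose and 0 fell, or 15 and 1 adjusted over the list alone (median log2 fold change 0.21, camera adjusted p = 7.58e-05, adjusted p = 0.142 with an estimated correlation). FDPS rose by 0.11 ± 0.037, and from the unstranded counts its log2 fold change was -0.0038 (adjusted p = 0.957). That call also ended without SREBF2 KO control 2 (0.0513) or starved 2 (0.132). STARD4 rose 1.73-fold and MYLIP fell 2.87-fold (-1.52 ± 0.11). LXR targets, which respond to oxysterols, fell: 1 of 8 genes rose and 5 fell (median log2 fold change -0.33, camera adjusted p = 0.0220, adjusted p = 0.0710 with an estimated correlation). ABCA1, the cholesterol exporter, fell 4.55-fold (-2.19 ± 0.19), from 5.92 ± 0.238 to 1.3 ± 0.0642 CPM. SREBF1, which encodes SREBP-1, fell 1.89-fold (-0.92 ± 0.04). Fatty acid genes gave 4 up and 9 down (camera adjusted p = 0.152), with ACSL3 (-0.87 ± 0.047), MID1IP1 (-0.47 ± 0.035) and SCD (-0.23 ± 0.038) lower.

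ATF4 targets fell in SREBF2 KO as well: 0 of 24 genes rose and 23 fell (median log2 fold change -0.92, camera adjusted p = 1.51e-25). ASNS fell 3.70-fold (-1.89 ± 0.043) and PSAT1 3.22-fold (-1.69 ± 0.043). Of the G2/M genes, 1 of 15 genes rose and 14 fell (median log2 fold change -0.36, camera adjusted p = 2.25e-07, adjusted p = 0.0534 with an estimated correlation). Of the G1/S genes, 2 of 17 genes rose and 12 fell (median log2 fold change -0.19, camera adjusted p = 1.12e-04, adjusted p = 0.0710 with an estimated correlation). For YAP and TAZ targets, 1 of 13 genes rose and 12 fell (median log2 fold change -0.56, camera adjusted p = 5.11e-05, adjusted p = 0.0534 with an estimated correlation). Examples were AJUBA (-0.88 ± 0.048), CYR61 (-1.09 ± 0.07) and CTGF (-1.78 ± 0.15). Oxidative phosphorylation genes rose: 14 of 17 genes rose and 1 fell, or 15 and 1 adjusted over the list alone (median log2 fold change 0.17, camera adjusted p = 2.25e-04, adjusted p = 0.269 with an estimated correlation). Examples were NDUFS3 (0.64 ± 0.06) and SDHB (0.36 ± 0.043) of complexes I and II. PPAR targets and fatty acid oxidation and lysosome genes also rose in part. In the first list 11 of 13 genes rose and 1 fell (median log2 fold change 0.20, camera adjusted p = 0.00308, adjusted p = 0.123 with an estimated correlation). In the second list 12 of 20 genes rose and 3 fell, or 12 and 4 adjusted over the list alone (median log2 fold change 0.21, camera adjusted p = 0.00381, adjusted p = 0.0534 with an estimated correlation). For fibroblast and mesenchymal markers, 0 of 8 genes rose and 6 fell (median log2 fold change -0.37, camera adjusted p = 0.0150, adjusted p = 0.0710 with an estimated correlation). The largest rises were ATP8B4 11.5-fold, OLIG3 9.19-fold, SYN1 8.51-fold, RASGRF2 7.77-fold, RBM47 7.19-fold and RGS2 6.42-fold, and the largest falls MT1E 9.25-fold, ZNF619 6.96-fold, LRRC31 6.58-fold, GPR1 5.92-fold, INHBE 5.92-fold and TUNAR 5.90-fold. In all, 4279 genes rose and 4644 fell, 527 and 548 by at least 2-fold, and 849 passed the test against a fold of 1.5.

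**Figure D2:**
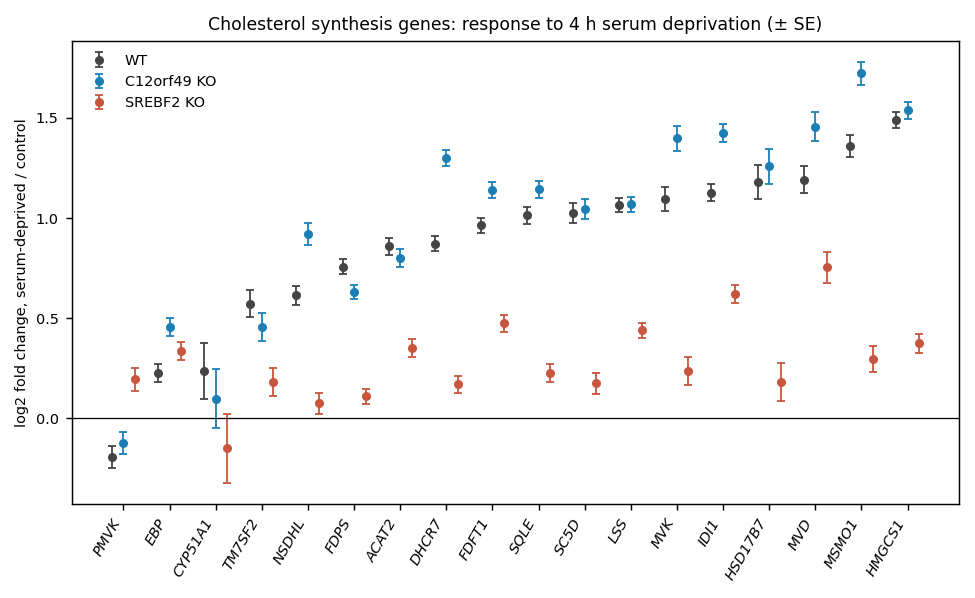
Log2 fold change (± SE, n = 3 per group) of 18 of the 20 cholesterol synthesis genes after 4 h without serum in WT, C12orf49 KO and SREBF2 KO. The medians over the whole list were 0.94, 1.06 and 0.21.

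Genes that moved without serum overlapped between the genotypes, least for WT and SREBF2 KO. Of the 4218 genes that rose in WT, 2914 also rose in C12orf49 KO, against 1161 by chance, 2841 fell in both, against 1152, and 376 moved in opposite directions. For WT and SREBF2 KO, 2027 rose in both, against 1020, 2285 fell in both, against 1064, and 1051 moved in opposite directions. For the 2 knockouts these were 2846 (1178 by chance), 3246 (1319) and 400. Genes such as HMGCS1, ASNS, MT1E, OLIG3 and ATP8B4 moved the same way in each genotype. Across genes, which are not independent replicates, the log2 responses had r = 0.697 for WT and C12orf49 KO, 0.571 for WT and SREBF2 KO and 0.700 for the knockouts.

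The serum response of C12orf49 KO differed from that of WT in 10 lists by camera at the preset correlation, none of which passed at an estimated correlation. HSPA1A and HSPA1B, near-identical heat shock paralogs between which reads are hard to assign, rose more in the knockout by 1.74 ± 0.10 and 1.59 ± 0.069. The differences of HSPA8P9 (1.56 ± 0.28) and HSPA8P8 (1.53 ± 0.23), pseudogenes of HSPA8, are uncertain for the same reason. ATF4 targets fell further in the knockout: 0 of 24 genes were higher and 19 lower, or 0 and 20 adjusted over the list alone (median log2 difference -0.57, camera adjusted p = 3.37e-16, adjusted p = 0.0953 with an estimated correlation). TRIB3, a pseudokinase of the stress response, differed by -1.16 ± 0.083 (edgeR adjusted p = 2.45e-11), DDIT3 by -1.15 ± 0.11, ATF5 by -1.87 ± 0.10 and MTHFD2 by -0.49 ± 0.049. FOXO targets had lower responses: 0 of 18 genes were higher and 11 lower (median log2 difference -0.30, camera adjusted p = 1.62e-04, adjusted p = 0.0953 with an estimated correlation). Examples were KLHL24 (-0.81 ± 0.10), CCNG2 (-0.51 ± 0.074) and CDKN1B (-0.31 ± 0.053). For ribosome biogenesis, 11 of 18 genes were higher and 0 lower, or 14 and 0 adjusted over the list alone (median log2 difference 0.19, camera adjusted p = 1.47e-05, adjusted p = 0.148 with an estimated correlation). For lysosome genes, 10 of 20 genes were higher and 0 lower, or 13 and 1 adjusted over the list alone (median log2 difference 0.17, camera adjusted p = 9.30e-04, adjusted p = 0.0733 with an estimated correlation). The glycolytic genes LDHA (0.42 ± 0.047) and ALDOA (0.36 ± 0.05) and the glucose carrier SLC2A1 (0.48 ± 0.058) had higher responses in the knockout. In that list 7 of 16 genes were higher and 1 lower, or 8 and 3 adjusted over the list alone (median log2 difference 0.18, camera adjusted p = 0.00759, adjusted p = 0.198 with an estimated correlation).

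Cholesterol genes responded somewhat more in C12orf49 KO than in WT: 8 of 20 genes were higher and 0 lower, or 9 and 1 adjusted over the list alone (median log2 difference 0.10, camera adjusted p = 0.00477, adjusted p = 0.290 with an estimated correlation). DHCR7, the last step to cholesterol, differed by 0.43 ± 0.055, IDI1 by 0.30 ± 0.06 and MSMO1 by 0.36 ± 0.078. ABCA1 rose in WT (0.94 ± 0.11) and its response was lower in the knockout by -0.93 ± 0.17. For oxidative phosphorylation, 4 of 17 genes were higher and 0 lower (median log2 difference 0.12, camera adjusted p = 0.00541, adjusted p = 0.387 with an estimated correlation). For G1/S genes, 8 of 17 genes were higher and 0 lower, or 8 and 1 adjusted over the list alone (median log2 difference 0.12, camera adjusted p = 0.00556, adjusted p = 0.234 with an estimated correlation). For fibroblast and mesenchymal markers, 0 of 8 genes were higher and 4 lower, or 0 and 5 adjusted over the list alone (median log2 difference -0.22, camera adjusted p = 0.0149, adjusted p = 0.0953 with an estimated correlation). For actin and SRF targets, 5 of 14 genes were higher and 1 lower, or 6 and 1 adjusted over the list alone (median log2 difference 0.06, camera adjusted p = 0.0427, adjusted p = 0.290 with an estimated correlation). That call ended without any of 4 libraries in turn (camera adjusted p = 0.0866 without WT starved 3, 0.0592 without C12orf49 KO control 1, and 0.0747 and 0.0749 without C12orf49 KO starved 2 and 3) and without the chromosome segments (0.114). The largest positive difference was that of COL11A1 (3.24 ± 0.50, or 7.08 without C12orf49 KO control 3, the only library of its group with reads of it), and the largest negative ones were those of ZNF619 (-2.31 ± 0.33), AKNA (-2.17 ± 0.15), GPR1 (-1.98 ± 0.28) and UNC5B (-1.92 ± 0.25). In all, 2287 responses were higher in C12orf49 KO and 2537 lower than in WT, and 83 passed the test against a fold of 1.5.

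The sterol genes responded less in SREBF2 KO than in WT. For cholesterol synthesis, 1 of 20 genes was higher and 17 lower (median log2 difference -0.64, camera adjusted p = 1.76e-16). HMGCS1 differed by -1.11 ± 0.062 (edgeR adjusted p = 2.00e-16) and SQLE by -0.79 ± 0.061. PMVK differed the other way (0.39 ± 0.079). For sterol uptake and transport, 0 of 11 genes were higher and 9 lower, or 0 and 10 adjusted over the list alone (median log2 difference -0.52, camera adjusted p = 5.05e-07). ABCA1 differed by -3.13 ± 0.23, from a rise in WT to a fall in the knockout. INSIG1 differed by -0.96 ± 0.077 and SREBF1 by -0.69 ± 0.055. For SREBP machinery, 2 of 11 genes were higher and 6 lower, or 2 and 7 adjusted over the list alone (median log2 difference -0.19, camera adjusted p = 0.00489, adjusted p = 0.0781 with an estimated correlation). For fatty acid synthesis and desaturation, 1 of 21 genes was higher and 13 lower, or 1 and 14 adjusted over the list alone (median log2 difference -0.38, camera adjusted p = 1.93e-07, adjusted p = 0.0507 with an estimated correlation). Examples were SCD (-0.84 ± 0.054), FADS1 (-0.91 ± 0.059), ACSL3 (-0.76 ± 0.066) and ACLY (-0.58 ± 0.052). For LXR targets, 1 of 8 genes was higher and 5 lower (median log2 difference -0.44, camera adjusted p = 0.00835, adjusted p = 0.0598 with an estimated correlation).

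Other groups also responded differently in SREBF2 KO. Oxidative phosphorylation genes had higher responses than in WT: 14 of 17 genes were higher and 0 lower (median log2 difference 0.30, camera adjusted p = 1.95e-07, adjusted p = 0.123 with an estimated correlation). Examples were NDUFV1 (0.52 ± 0.064) and SDHB (0.44 ± 0.06). For ribosome biogenesis, 13 of 18 genes were higher and 2 lower (median log2 difference 0.31, camera adjusted p = 2.50e-06, adjusted p = 0.0904 with an estimated correlation). Examples were BOP1 (0.45 ± 0.059) and PES1 (0.44 ± 0.062). For FOXO targets, 0 of 18 genes were higher and 10 lower, or 1 and 11 adjusted over the list alone (median log2 difference -0.31, camera adjusted p = 1.83e-04, adjusted p = 0.0781 with an estimated correlation). Examples were KLHL24 (-0.81 ± 0.099), INSR (-0.56 ± 0.075) and BCL6 (-0.82 ± 0.12), where INSR lies in the chromosome 19 segment. For G1/S genes, 8 of 17 genes were higher and 1 lower (median log2 difference 0.15, camera adjusted p = 0.00210, adjusted p = 0.123 with an estimated correlation). ID1 and ID3, inhibitors of basic helix-loop-helix factors, were higher by 1.85 ± 0.14 and 1.61 ± 0.079, and the ETS factor ETV4 by 1.56 ± 0.21. The immediate early gene EGR1 was higher by 1.15 ± 0.18. In its list 10 of 22 genes were higher and 3 lower, or 11 and 3 adjusted over the list alone (median log2 difference 0.32, camera adjusted p = 0.0240, adjusted p = 0.118 with an estimated correlation). The call ended from the unstranded counts (camera adjusted p = 0.0846) and without WT control 3 (0.0502). For ATF4 targets, 7 of 24 genes were higher and 3 lower, or 8 and 3 adjusted over the list alone (median log2 difference 0.08, camera adjusted p = 0.0166, adjusted p = 0.434 with an estimated correlation), or an adjusted p of 0.128 without WT control 3. The largest negative differences after ABCA1 were MAP2 (-1.88 ± 0.15), CSMD3 (-1.69 ± 0.20) and PCDH19 (-1.63 ± 0.23). In all, 2761 responses were higher and 3240 lower than in WT, and 45 passed the test against a fold of 1.5. The SREBF2 KO starved libraries also had more unmapped reads than their controls, and the effect of this on the responses was not tested.

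C12orf49 KO had higher sterol gene responses than SREBF2 KO. For cholesterol synthesis, 17 of 20 genes were higher and 1 lower (median log2 difference 0.82, camera adjusted p = 9.79e-25). Examples were MSMO1 (1.42 ± 0.087), HMGCS1 (1.16 ± 0.064) and DHCR7 (1.13 ± 0.057). For sterol uptake and transport, 7 of 11 genes were higher and 1 lower, or 9 and 1 adjusted over the list alone (median log2 difference 0.52, camera adjusted p = 1.97e-06). Examples were TMEM97 (0.75 ± 0.063) and ABCA1 (2.20 ± 0.23, down in SREBF2 KO). For fatty acid synthesis and desaturation, 15 of 21 genes were higher and 1 lower, or 15 and 2 adjusted over the list alone (median log2 difference 0.36, camera adjusted p = 1.43e-10), and SCD (0.79 ± 0.054), FADS1 (0.82 ± 0.059) and ACLY (0.61 ± 0.052) were among the higher responses. For SREBP machinery, 6 of 11 genes were higher and 0 lower, or 6 and 1 adjusted over the list alone (median log2 difference 0.22, camera adjusted p = 0.00371, adjusted p = 0.0616 with an estimated correlation). For LXR targets, 4 of 8 genes were higher and 1 lower, or 4 and 2 adjusted over the list alone (median log2 difference 0.36, camera adjusted p = 0.0287, adjusted p = 0.0698 with an estimated correlation). ATF4 targets had lower responses in C12orf49 KO: 0 of 24 genes were higher and 21 lower, or 0 and 22 adjusted over the list alone (median log2 difference -0.56, camera adjusted p = 1.11e-25). Examples were DDIT3 (-1.62 ± 0.11), CEBPB (-1.5 ± 0.097), TRIB3 (-1.3 ± 0.082) and CHAC1 (-1.22 ± 0.089). For ERK output genes, 0 of 15 genes were higher and 7 lower, or 1 and 7 adjusted over the list alone (median log2 difference -0.58, camera adjusted p = 0.00228, adjusted p = 0.0698 with an estimated correlation), with ETV4 lower by 6.83-fold and ETV5 by 2.57-fold. For oxidative phosphorylation, 2 of 17 genes were higher and 8 lower (median log2 difference -0.18, camera adjusted p = 0.00360, adjusted p = 0.446 with an estimated correlation). For lysosome genes, 9 of 20 genes were higher and 1 lower (median log2 difference 0.07, camera adjusted p = 0.00528), and camera gave an adjusted p of 0.0678 without the chromosome segments. COL11A1 (3.81 ± 0.47, or 7.65 without C12orf49 KO control 3), BHLHE22 (1.99 ± 0.20) and CSMD3 (1.76 ± 0.19) were also higher, and SPARCL1 (-2.12 ± 0.26), MYH15 (-2.02 ± 0.25) and TSC22D3 (-1.86 ± 0.11) lower. In all, 2562 responses were higher in C12orf49 KO and 2270 lower, and 106 passed the test against a fold of 1.5.

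At control, C12orf49 KO had lower cholesterol synthesis genes than WT. NSDHL (ENSG00000147383.10, chromosome X, 152830967 to 152869729), a C4 demethylation enzyme, was 2.73-fold lower (-1.45 ± 0.054), and it lies in the chromosome X segment that was lower in this line. HMGCS1 was 1.95-fold lower (-0.96 ± 0.043, edgeR adjusted p = 1.66e-21), MSMO1 1.81-fold (-0.86 ± 0.059), and FDFT1 1.43-fold (-0.51 ± 0.04). In the list, 0 of 20 genes were higher and 16 lower (median log2 fold change -0.40, camera adjusted p = 6.87e-14). For sterol uptake and transport, 0 of 11 genes were higher and 7 lower (median log2 fold change -0.16, camera adjusted p = 0.0128, adjusted p = 0.0665 with an estimated correlation). INSIG1 was 1.66-fold lower (-0.73 ± 0.057). For SREBP machinery, 0 of 11 genes were higher and 5 lower, or 1 and 5 adjusted over the list alone (median log2 fold change -0.05, camera adjusted p = 0.0213, adjusted p = 0.134 with an estimated correlation). For glycerolipid and phospholipid synthesis, 0 of 18 genes were higher and 7 lower, or 0 and 8 adjusted over the list alone (median log2 fold change -0.10, camera adjusted p = 0.0213, adjusted p = 0.0665 with an estimated correlation). Fatty acid synthesis gave 4 higher and 6 lower, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.216). For PPAR targets and fatty acid oxidation, 9 of 13 genes were higher and 0 lower (median log2 fold change 0.18, camera adjusted p = 0.00627, adjusted p = 0.134 with an estimated correlation).

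ATF4 targets were higher in C12orf49 KO at control: 23 of 24 genes were higher and 0 lower (median log2 fold change 0.79, camera adjusted p = 3.92e-36). DDIT3, which encodes CHOP, was 3.09-fold higher (1.63 ± 0.072), ASNS 1.85-fold (0.89 ± 0.041), SHMT2 1.75-fold (0.81 ± 0.036) and MTHFD2 1.70-fold (0.77 ± 0.035). Fibroblast and mesenchymal markers were higher: 7 of 8 genes were higher and 0 lower (median log2 fold change 0.51, camera adjusted p = 4.96e-08). Examples were FN1 (1.19 ± 0.10), THY1 (0.93 ± 0.13), CDH2 (0.77 ± 0.042) and VIM (0.49 ± 0.035). For G1/S genes, 9 of 17 genes were higher and 2 lower, or 12 and 2 adjusted over the list alone (median log2 fold change 0.11, camera adjusted p = 6.50e-05, adjusted p = 0.0665 with an estimated correlation), and TYMS, thymidylate synthase, was 2.05-fold higher. For ERK output genes, 9 of 15 genes were higher and 1 lower (median log2 fold change 0.38, camera adjusted p = 0.00557, adjusted p = 0.108 with an estimated correlation). For actin and SRF targets, 2 of 14 genes were higher and 6 lower, or 2 and 7 adjusted over the list alone (median log2 fold change -0.11, camera adjusted p = 0.00939, adjusted p = 0.146 with an estimated correlation), where FLNA (-0.85 ± 0.049) lies in the X segment. Without the chromosome segments camera gave 0.0510. For FOXO targets, 6 of 18 genes were higher and 3 lower (median log2 fold change 0.11, camera adjusted p = 0.0338, adjusted p = 0.249 with an estimated correlation), or 0.127 without WT control 1 and 0.133 without that library and SREBF2 KO starved 1. The X-linked genes GLA, LAMP2, PGK1 and DKC1, in the same segment, were lower by 2.12-fold, 1.58-fold, 1.88-fold and 1.44-fold. LAYN, a hyaluronan receptor, had 0 reads in C12orf49 KO control and 1392 in WT control, at least 432-fold lower against a floor of 3 counts over the group. FBXO17, CGAS, COL11A1, TMEM47 and SGCD stood at 0.0406, 0.102, 0.0507, 0.224 and 0.203 CPM in C12orf49 KO control, against 8.89, 18.7, 7.32, 13.4 and 10.6 CPM in WT. The erythroid factor TAL1 was 10.6-fold lower, and AEBP1 38.9-fold, TFPI2 18.5-fold, COL9A1 12.3-fold, MYH15 8.92-fold, GNG11 7.52-fold and RAB34 7.12-fold higher. In all, 2665 genes were higher and 2912 lower, 335 and 401 by at least 2-fold, and 691 passed the test against a fold of 1.5.

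Without serum, C12orf49 KO still had lower sterol genes than WT. HMGCS1 was 1.88-fold lower (-0.91 ± 0.04, edgeR adjusted p = 7.91e-22), NSDHL, in the X segment, 2.21-fold (-1.14 ± 0.049), MSMO1 1.41-fold (-0.49 ± 0.051) and INSIG1 1.54-fold (-0.63 ± 0.049). In the cholesterol list 0 of 20 genes were higher and 13 lower (median log2 fold change -0.25, camera adjusted p = 1.47e-07, adjusted p = 0.111 with an estimated correlation). For sterol uptake and transport, 1 of 11 genes was higher and 7 lower, or 1 and 8 adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 0.00544, adjusted p = 0.0564 with an estimated correlation). ABCA1 was 1.95-fold lower (-0.96 ± 0.11) and SOAT1, which esterifies cholesterol, 1.40-fold (-0.49 ± 0.04). For SREBP machinery, 2 of 11 genes were higher and 5 lower, or 2 and 6 adjusted over the list alone (median log2 fold change -0.10, camera adjusted p = 0.0420, adjusted p = 0.231 with an estimated correlation), or an adjusted p of 0.0636 without WT starved 1. MBTPS2, the X-linked site-2 protease gene, was 1.53-fold lower. ATF4 targets were still higher: 17 of 24 genes were higher and 1 lower (median log2 fold change 0.31, camera adjusted p = 2.63e-07, adjusted p = 0.231 with an estimated correlation). G1/S genes were higher as well: 14 of 17 genes were higher and 0 lower (median log2 fold change 0.22, camera adjusted p = 3.47e-08, adjusted p = 0.0564 with an estimated correlation). For ribosome biogenesis, 11 of 18 genes were higher and 1 lower (median log2 fold change 0.17, camera adjusted p = 0.00826, adjusted p = 0.369 with an estimated correlation). For oxidative phosphorylation, 8 of 17 genes were higher and 0 lower (median log2 fold change 0.16, camera adjusted p = 0.00256, adjusted p = 0.369 with an estimated correlation). For PPAR targets and fatty acid oxidation, 8 of 13 genes were higher and 0 lower (median log2 fold change 0.12, camera adjusted p = 0.00544, adjusted p = 0.231 with an estimated correlation). For fibroblast and mesenchymal markers, 5 of 8 genes were higher and 1 lower (median log2 fold change 0.38, camera adjusted p = 0.00544, adjusted p = 0.0564 with an estimated correlation). LAYN had 0 reads in C12orf49 KO and 750 in WT, at least 288-fold lower on the same floor, and FBXO17 had 1 read in C12orf49 KO and 591 in WT. AEBP1 was 34.9-fold higher and the receptor tyrosine kinase AXL 8.09-fold. In all, 3661 genes were higher and 4062 lower, 328 and 667 by at least 2-fold, and 819 passed the test against a fold of 1.5.

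At control, SREBF2 KO had lower cholesterol synthesis genes than WT. HMGCS1 was 3.54-fold lower (-1.82 ± 0.045, edgeR adjusted p = 3.52e-30), FDFT1 2.63-fold (-1.40 ± 0.041) and SQLE, squalene epoxidase, 2.21-fold (-1.14 ± 0.044). In the list, 0 of 20 genes were higher and 18 lower, or 0 and 19 adjusted over the list alone (median log2 fold change -0.73, camera adjusted p = 1.24e-30). For sterol uptake and transport, 0 of 11 genes were higher and 5 lower, or 1 and 5 adjusted over the list alone (median log2 fold change -0.09, camera adjusted p = 0.00469), with STARD4 1.59-fold lower (-0.67 ± 0.067). INSIG1 was 1.62-fold lower (-0.70 ± 0.056). For fatty acid synthesis and desaturation, 2 of 21 genes were higher and 8 lower (median log2 fold change -0.06, camera adjusted p = 0.00361, adjusted p = 0.174 with an estimated correlation). Examples were SLC25A1 (-0.40 ± 0.04), SCD (-0.35 ± 0.038) and FASN (-0.34 ± 0.04). For LXR targets, 1 of 8 genes was higher and 5 lower (median log2 fold change -0.32, camera adjusted p = 0.00779, adjusted p = 0.0611 with an estimated correlation). SREBF1 and ABCA1 were lower (-0.45 ± 0.038 and -0.81 ± 0.13) and APOE, apolipoprotein E, 2.83-fold higher.

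Other groups differed in SREBF2 KO at control too. Lysosome genes were higher: 12 of 20 genes were higher and 1 lower (median log2 fold change 0.16, camera adjusted p = 1.73e-04), with MCOLN1 (0.75 ± 0.071) in the chromosome 19 segment and PSAP and CTSB (0.21 ± 0.035 and 0.22 ± 0.039) outside it. For FOXO targets, 9 of 18 genes were higher and 0 lower, or 11 and 1 adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 2.35e-04, adjusted p = 0.0752 with an estimated correlation). Examples were GADD45A (1.33 ± 0.089) and KLHL24 (0.68 ± 0.073), and INSR (0.66 ± 0.053) in that segment. For ATF4 targets, 10 of 24 genes were higher and 1 lower (median log2 fold change 0.11, camera adjusted p = 7.15e-04, adjusted p = 0.338 with an estimated correlation). NUPR1 was 5.01-fold and GDF15 7.55-fold higher. For ribosome biogenesis, 1 of 18 genes was higher and 10 lower, or 1 and 15 adjusted over the list alone (median log2 fold change -0.12, camera adjusted p = 1.73e-04, adjusted p = 0.142 with an estimated correlation). PPAN, in the segment, was higher (0.48 ± 0.12). For G1/S genes, 0 of 17 genes were higher and 8 lower, or 0 and 9 adjusted over the list alone (median log2 fold change -0.12, camera adjusted p = 2.35e-04, adjusted p = 0.0852 with an estimated correlation). For interferon-stimulated genes, 1 of 13 genes was higher and 5 lower (median log2 fold change -0.45, camera adjusted p = 0.00776, adjusted p = 0.0752 with an estimated correlation). Examples were BST2 (-0.46 ± 0.052) and IFIT1 (-1.11 ± 0.14). For epithelial markers, 3 of 8 genes were higher and 0 lower (median log2 fold change 0.22, camera adjusted p = 0.0488, adjusted p = 0.115 with an estimated correlation), or 0.0572 from the unstranded counts, 0.0506 without WT control 3 and 0.0747 without SREBF2 KO control 1; KRT8 was 2.53-fold higher. The surface protein THY1 was 6.44-fold lower and the globin HBA1, whose reads are hard to tell from those of HBA2, 3.31-fold higher. Among the largest differences downward were HCLS1 60.4-fold, THSD7B 51.1-fold, SLC17A9 51.0-fold and DDIT4L 41.1-fold. COL11A1 was 38.5-fold higher, and TFPI2 22.4-fold, TMEM47 13.3-fold, GNG11 9.73-fold, GALNT5 9.55-fold and FCGRT 8.57-fold. In all, 2512 genes were higher and 1970 lower, 335 and 322 by at least 2-fold, and 492 passed the test against a fold of 1.5.

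Without serum, genes of cholesterol and fatty acid synthesis and of sterol uptake in SREBF2 KO lay further below those of WT than at control. HMGCS1 was 7.65-fold lower (-2.93 ± 0.044, edgeR adjusted p = 6.74e-38), SQLE 3.81-fold (-1.93 ± 0.043) and FDFT1 3.70-fold (-1.89 ± 0.041). In the list, 1 of 20 genes was higher and 19 lower (median log2 fold change -1.31, camera adjusted p = 8.30e-27), and the gene that was higher was PMVK (0.29 ± 0.056). For sterol uptake and transport, 0 of 11 genes were higher and 10 lower (median log2 fold change -0.56, camera adjusted p = 1.13e-08). ABCA1 was 15.3-fold lower (-3.94 ± 0.17) and STARD4 2.31-fold (-1.21 ± 0.059). INSIG1 was 3.16-fold and SREBF1 2.20-fold lower. For SREBP machinery, 3 of 11 genes were higher and 5 lower (median log2 fold change -0.05, camera adjusted p = 0.0214, adjusted p = 0.116 with an estimated correlation). For fatty acid synthesis and desaturation, 2 of 21 genes were higher and 16 lower, or 2 and 17 adjusted over the list alone (median log2 fold change -0.47, camera adjusted p = 2.34e-09). Examples were SCD (-1.19 ± 0.038), FADS1 (-1.03 ± 0.042), FASN (-0.76 ± 0.041) and ACLY (-0.63 ± 0.037). For LXR targets, 1 of 8 genes was higher and 5 lower, or 2 and 5 adjusted over the list alone (median log2 fold change -0.77, camera adjusted p = 0.0104).

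Immediate early genes were higher in SREBF2 KO than in WT without serum: 14 of 22 genes were higher and 3 lower (median log2 fold change 0.43, camera adjusted p = 0.00334). Examples were EGR1 (1.74 ± 0.12), JUN (1.08 ± 0.13) and IER5 (0.73 ± 0.07). For ERK output genes, 7 of 15 genes were higher and 1 lower (median log2 fold change 0.36, camera adjusted p = 0.0443, adjusted p = 0.222 with an estimated correlation), or 0.0841 without WT starved 3 and 0.0915 without SREBF2 KO starved 1 (0.114 without that library and WT control 1), and ETV4 was 2.90-fold higher. For oxidative phosphorylation, 14 of 17 genes were higher and 2 lower (median log2 fold change 0.25, camera adjusted p = 6.45e-05, adjusted p = 0.222 with an estimated correlation). For ATF4 targets, 19 of 24 genes were higher and 3 lower (median log2 fold change 0.30, camera adjusted p = 2.56e-05, adjusted p = 0.222 with an estimated correlation), with CHAC1 2.18-fold higher. For endoplasmic reticulum chaperones, 11 of 19 genes were higher and 4 lower, or 13 and 4 adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 0.0169, adjusted p = 0.116 with an estimated correlation). For lysosome genes, 12 of 20 genes were higher and 5 lower, or 12 and 6 adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 0.0214, adjusted p = 0.107 with an estimated correlation). For ribosome biogenesis, 13 of 18 genes were higher and 4 lower (median log2 fold change 0.18, camera adjusted p = 0.0169, adjusted p = 0.278 with an estimated correlation). For epithelial markers, 4 of 8 genes were higher and 0 lower (median log2 fold change 0.32, camera adjusted p = 0.0372, adjusted p = 0.108 with an estimated correlation), or 0.0676 without WT starved 3, with the keratins KRT8 and KRT18 3.41-fold and 1.68-fold higher. Fibroblast and mesenchymal markers were lower: 0 of 8 genes were higher and 4 lower (median log2 fold change -0.22, camera adjusted p = 0.0443, adjusted p = 0.116 with an estimated correlation). That call ended from the unstranded counts (0.0846), without WT starved 1 (0.0558), without SREBF2 KO starved 1 or 2 (0.0553 and 0.0506), without SREBF2 KO starved 1 and WT control 1 together (0.0522) and without the segments (0.0515). SERPINB9, an inhibitor of granzyme B, was 36.0-fold lower, and the zinc finger gene ZNF544 10.8-fold higher. In all, 4295 genes were higher and 4433 lower, 541 and 509 by at least 2-fold, and 800 passed the test against a fold of 1.5.

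Between the knockouts, C12orf49 KO had the higher cholesterol synthesis genes at control. HMGCS1 was 1.81-fold higher than in SREBF2 KO (0.86 ± 0.046, edgeR adjusted p = 5.49e-19) and FDFT1 1.85-fold (0.88 ± 0.042), while NSDHL, in the X segment, was 2.22-fold lower (-1.15 ± 0.055). In the list, 14 of 20 genes were higher and 2 lower, or 15 and 2 adjusted over the list alone (median log2 fold change 0.38, camera adjusted p = 1.21e-06, adjusted p = 0.112 with an estimated correlation). Sterol uptake and transport did not pass, with 4 of 11 genes higher and 3 lower (camera adjusted p = 0.735). For LXR targets, 5 of 8 genes were higher and 0 lower (median log2 fold change 0.19, camera adjusted p = 0.0368, adjusted p = 0.104 with an estimated correlation), or 0.0710 from the unstranded counts. ATF4 targets were higher: 21 of 24 genes were higher and 1 lower, or 22 and 1 adjusted over the list alone (median log2 fold change 0.62, camera adjusted p = 5.26e-21). Examples were DDIT3 (1.55 ± 0.072), TRIB3 (1.21 ± 0.056), MTHFD2 (0.69 ± 0.035) and SHMT2 (0.65 ± 0.036). For fibroblast and mesenchymal markers, 6 of 8 genes were higher and 0 lower, or 7 and 0 adjusted over the list alone (median log2 fold change 0.60, camera adjusted p = 4.31e-06), with THY1 12.3-fold and COL1A1 2.35-fold higher. For G1/S genes, 14 of 17 genes were higher and 1 lower, or 15 and 1 adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 5.32e-08). For PPAR targets and fatty acid oxidation, 8 of 13 genes were higher and 0 lower (median log2 fold change 0.18, camera adjusted p = 0.0120, adjusted p = 0.219 with an estimated correlation). Lysosome genes were lower: 2 of 20 genes were higher and 14 lower (median log2 fold change -0.19, camera adjusted p = 6.17e-05), with GLA and LAMP2 (-1.23 ± 0.054 and -0.74 ± 0.042) in the X segment and MCOLN1 (-0.87 ± 0.073) in the chromosome 19 segment. LAYN was at least 472-fold lower (0 reads against 1435), and TMEM47 829-fold lower. In all, 3457 genes were higher in C12orf49 KO and 3793 lower, 539 and 663 by at least 2-fold, and 1187 passed the test against a fold of 1.5.

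Without serum the gap between the knockouts widened for cholesterol synthesis genes. HMGCS1 was 4.06-fold higher in C12orf49 KO (2.02 ± 0.044, edgeR adjusted p = 1.87e-32), SQLE 3.02-fold (1.59 ± 0.043) and ABCA1 7.86-fold (2.98 ± 0.18). In the cholesterol list 17 of 20 genes were higher and 2 lower (median log2 fold change 1.15, camera adjusted p = 1.19e-16). In sterol uptake and transport 9 of 11 genes were higher and 1 lower (median log2 fold change 0.59, camera adjusted p = 1.39e-04). In fatty acid synthesis and desaturation 16 of 21 genes were higher and 2 lower (median log2 fold change 0.30, camera adjusted p = 5.26e-07). For LXR targets, 5 of 8 genes were higher and 2 lower, or 5 and 3 adjusted over the list alone (median log2 fold change 0.65, camera adjusted p = 0.0250, adjusted p = 0.0731 with an estimated correlation). For G1/S genes, 14 of 17 genes were higher and 1 lower (median log2 fold change 0.23, camera adjusted p = 1.03e-05). For fibroblast and mesenchymal markers, 6 of 8 genes were higher and 0 lower, or 7 and 0 adjusted over the list alone (median log2 fold change 0.53, camera adjusted p = 1.46e-04), with THY1 15.4-fold higher. Immediate early genes were lower: 2 of 22 genes were higher and 14 lower (median log2 fold change -0.25, camera adjusted p = 0.0166, adjusted p = 0.0884 with an estimated correlation). Examples were EGR1 (-1.18 ± 0.11), IER5 (-0.87 ± 0.069) and KLF4 (-1.93 ± 0.15). ATF4 targets gave 7 higher and 6 lower, a median of 0.03, a mean of -0.18 and a test that pointed up (camera adjusted p = 0.710). KRT8 was 4.72-fold and KRT18 1.83-fold lower, AXL 6.91-fold higher, and LAYN at least 291-fold lower (0 reads against 741). In all, 4517 genes were higher in C12orf49 KO and 4577 lower, 567 and 920 by at least 2-fold, and 1454 passed the test against a fold of 1.5.

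**Figure D3:**
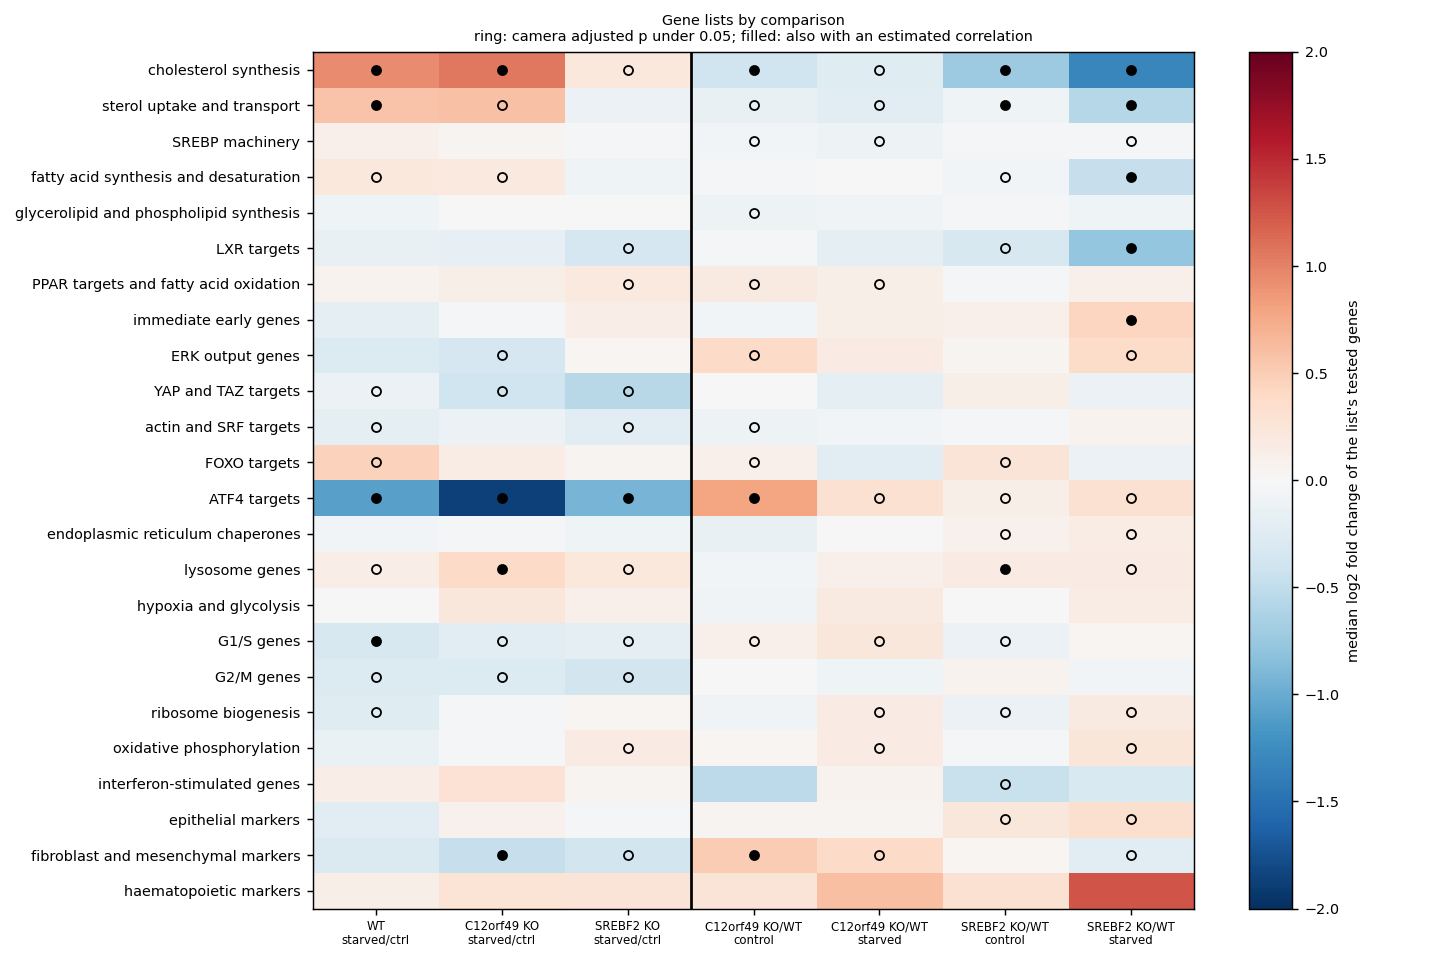
Median log2 fold change of each of the 24 gene lists (vertical axis) in the 3 responses and the 4 comparisons of a knockout with WT (horizontal axis); rings mark a camera adjusted p under 0.05 and filled circles one that also held with an estimated correlation. Over the 12 contrasts, 123 of 288 list tests passed camera, and 36 also passed with an estimated correlation.

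Some genes differed from WT in both knockouts. HMGCS1, FDFT1, SQLE, INSIG1 and ABCA1 were lower in both without serum, and TFPI2, a protease inhibitor, and GNG11, a G protein subunit, higher in both. At control, 659 genes were higher in both knockouts, against 378 for independent calls, 587 lower in both, against 324, and 862 were called in opposite directions, against 710.2. Without serum these were 1672 (889), 1813 (1018) and 1242 (1903). Across genes, which are not independent replicates, the log2 differences had r = 0.133 at control and 0.220 without serum. Comparisons with the same WT libraries share their chance values: simulated unchanged groups gave a mean r of 0.488 and 0.505 over 20 simulations, with a mean covariance of 0.0268 and 0.0293. The measured covariance was 0.0462 and 0.0955. With C12orf49 KO and SREBF2 KO taken from opposite treatments, which share no library, r was 0.0131 and -0.0118.

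Some differences from WT followed chromosome position. In C12orf49 KO, 262 genes with a mean log2 CPM above 2 on chromosome X between 55143102 (FAM104B) and 155669944 (TMLHE, hg38) had a median log2 fold change of -0.81 at control, 0.570 of WT, and -0.85 without serum. At control 95.4% of them were lower than in WT, and the 155 such genes on the rest of the chromosome, which include EBP, had a median of -0.22. The cholesterol gene NSDHL, FLNA, LAMP2, GLA, PGK1 and DKC1 lie in this segment. In SREBF2 KO, 219 such genes on chromosome 19 between 301444 (MIER2) and 11376951 (SWSAP1) had a median of 0.54 at control, 1.45 of WT, and 0.68 without serum, and 96.3% were higher at control. INSR, CNN2, MCOLN1 and PPAN lie there. The limits of the segments were set after the data were seen.

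**Figure D4:**
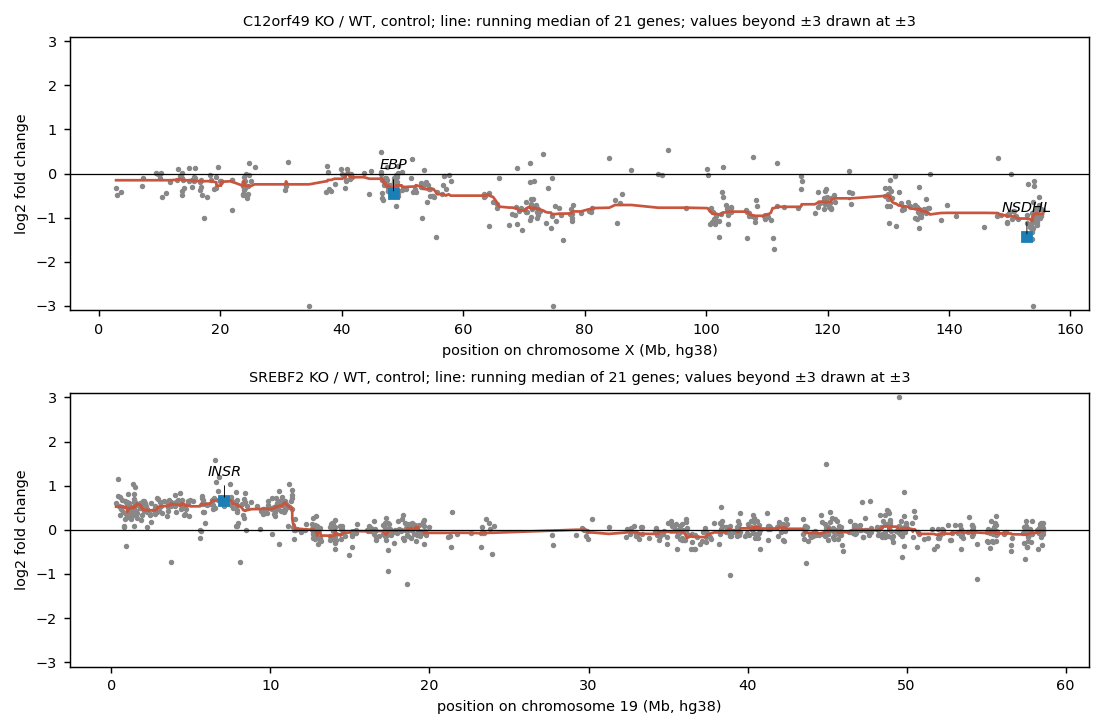
Log2 fold change against WT at control by position (Mb, hg38) on chromosome X in C12orf49 KO and on chromosome 19 in SREBF2 KO, each point a gene, with the running median of 21 genes as a line. The medians of the segments were -0.81 and 0.54; EBP, NSDHL and INSR are named.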

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

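The tests of the chromosome segments were chosen after these patterns were seen; the other groupings of the libraries were planned. The response to 4 h without serum differed between genotypes by a test of the difference itself. 4824 genes differed between C12orf49 KO and WT, 6001 between SREBF2 KO and WT, and 4832 between C12orf49 KO and SREBF2 KO. Median log2 differences of the lists that passed camera are given with the adjusted p at an estimated correlation in brackets where that p was above 0.05. For C12orf49 KO against WT they were cholesterol synthesis 0.10 (0.290), actin and SRF targets 0.061 (0.290), FOXO targets -0.30 (0.0953), ATF4 targets -0.57 (0.0953), lysosome genes 0.17 (0.0733), hypoxia and glycolysis 0.18 (0.198), G1/S genes 0.12 (0.234), ribosome biogenesis 0.19 (0.148), oxidative phosphorylation 0.12 (0.387) and fibroblast and mesenchymal markers -0.22 (0.0953). For SREBF2 KO against WT they were cholesterol synthesis -0.64, sterol uptake and transport -0.52, SREBP machinery -0.19 (0.0781), fatty acid synthesis and desaturation -0.38 (0.0507), LXR targets -0.44 (0.0598), immediate early genes 0.32 (0.118), FOXO targets -0.31 (0.0781), ATF4 targets 0.076 (0.434), G1/S genes 0.15 (0.123), ribosome biogenesis 0.31 (0.0904) and oxidative phosphorylation 0.30 (0.123). For C12orf49 KO against SREBF2 KO they were cholesterol synthesis 0.82, sterol uptake and transport 0.52, SREBP machinery 0.22 (0.0616), fatty acid synthesis and desaturation 0.36, LXR targets 0.36 (0.0698), ERK output genes -0.58 (0.0698), ATF4 targets -0.56, lysosome genes 0.074 and oxidative phosphorylation -0.18 (0.446). Of these calls, alternatives ended that of actin and SRF targets (camera adjusted p up to 0.114, without the segments), those of ATF4 targets (0.128 without WT control 3) and immediate early genes (0.0502 without WT control 3, 0.0846 from the unstranded counts) in SREBF2 KO against WT, and that of lysosome genes between the knockouts (0.0678 without the segments).

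For each comparison of 2 groups, the 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 1 of 10 results as large in each, from 4482 to 9896 called genes, and the highest other split gave 0 by edgeR in all 9 comparisons. At an unadjusted p under 0.05 the other splits gave 458 to 2026 genes for the response of WT, 416 to 864 for C12orf49 KO and 499 to 1199 for SREBF2 KO. They gave 493 to 1239 and 450 to 1498 for C12orf49 KO against WT at control and without serum, 506 to 1180 and 546 to 2261 for SREBF2 KO against WT, and 454 to 891 and 448 to 2036 for C12orf49 KO against SREBF2 KO. The other tool run, DESeq2, was not applied to the other splits. For the differences between responses, 100 groupings of the 12 libraries were counted, the real one included. 2 of 100 gave as many genes as the real 4824 for C12orf49 KO and WT (highest other 7762), 3 of 100 as many as 6001 for SREBF2 KO and WT (highest other 7849), and 6 of 100 as many as 4832 for C12orf49 KO and SREBF2 KO (highest other 9497). The other groupings that reached the real counts exchanged genotypes within 1 treatment only, which measures the difference between genotypes, so they point to the structure of the samples. The 85 groupings that mixed genotypes in both treatments gave 0 genes in each case. These counts therefore do not decide whether chance can be excluded.

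In C12orf49 KO, the 262 genes with a mean log2 CPM above 2 on chromosome X from 55143102 to 155669944 had a median log2 fold change of -0.81 against WT at control, found in the control libraries. Library normalization or depth is argued against: the largest median of another chromosome was 0.0774 in size. The 155 other genes of chromosome X above that level had a median of -0.22 at control, so lower values were not limited to the segment. A candidate explanation, not tested on DNA, is fewer copies of the segment in the C12orf49 KO cells. In the serum-free libraries, which were not used to find it, 92.7% of its genes were lower than in WT. Its median response differed from that of WT by -0.02. Those libraries share the knockout, so regulation by genotype would give this as well. HAP1 is near-haploid and the ploidy of the line was not measured, so 0.570 of WT cannot be read as a copy number. Regulation of the segment's genes by the loss of C12orf49 (median -0.81) and a difference carried by the line cannot be told apart. The labels name no C12orf49 KO clone.

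In SREBF2 KO, the 219 genes with a mean log2 CPM above 2 on chromosome 19 from 301444 to 11376951 had a median log2 fold change of 0.54 against WT at control. Library normalization or depth is argued against: the largest median of another chromosome was 0.0835 in size. A candidate explanation, not tested on DNA, is an extra copy of this segment in the SREBF2 KO cells. In the serum-free libraries 97.3% of its genes were higher than in WT, with a median difference of 0.13 between responses. Those libraries share the knockout, so regulation by genotype would give this as well. The ploidy of the line was not measured, so 1.45 of WT cannot be read as a copy number. Regulation of the segment's genes by the loss of SREBF2 (median 0.54) and a difference carried by the line cannot be told apart. The labels name no SREBF2 KO clone.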

How the results depend on the processing

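Tests added after the data were seen are those without WT control 1 and SREBF2 KO starved 1, the 2 libraries with the most detected genes, and those without the genes of the 2 chromosome segments; the other alternatives were planned. Outside the test against a fold of 1.5, the counts of called genes in the 12 contrasts stayed within 1.5 times their values. The ratios ran from 0.892 without a filter on low counts to 1.10 with only the libraries compared. Leaving out 1 library gave ratios from 0.801 (SREBF2 KO against WT at control without SREBF2 KO control 2, 3590 genes instead of 4482) to 1.05. Without the 2 libraries with the most detected genes they were 0.878 to 1.11, and without the segments 0.908 to 0.961. Which side held more calls depended on the processing: the larger side changed in 4 of 12 contrasts with library size alone and in 4 without a filter on low counts. For SREBF2 KO against WT at control, library size alone gave 2186 higher and 2365 lower instead of 2512 and 1970. For the difference between the responses of the knockouts, the data without a filter gave 1993 and 2316 instead of 2562 and 2270, and the data without the segments 2241 and 2321. By construction, the test against a fold of 1.5 called fewer genes. In the responses it left 712 in WT, 1964 in C12orf49 KO and 849 in SREBF2 KO. At control and without serum it left 691 and 819 for C12orf49 KO against WT, 492 and 800 for SREBF2 KO against WT, and 1187 and 1454 for C12orf49 KO against SREBF2 KO. For the differences between responses it left 83 (C12orf49 KO and WT), 45 (SREBF2 KO and WT) and 106 (C12orf49 KO and SREBF2 KO). Of 2625 calls within lists, it left 452.

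Of 288 list tests, 123 passed camera at a preset correlation, 36 at an estimated correlation and 226 with fry, which asks whether a list changed rather than whether it changed more than other genes. With the unstranded counts 121 passed, 119 of them among the 123 and in the same direction. Library size alone gave 125 (122 of the 123), the data without the 2 libraries 124 (120) and the data without the segments 122 (118). No list that passed camera turned its direction in any of these. Of 22599 alternative values for the 1304 called values of named genes, 253 were not called and 1 reversed; 66 genes lost a call at least once. The reversed value was that of FDPS in SREBF2 KO without serum, -0.0038 from the unstranded counts (adjusted p = 0.957) instead of 0.11, and the cause was not tested. The correlation between the 2 knockouts' differences from WT was 0.214 (control) and 0.281 (without serum) with called genes left out, and 0.0131 and -0.0118 for opposite treatments, which share no WT library.

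The labels number the replicates without saying that equal numbers belong together. With the number as a replicate block, 8194 genes instead of 8273 were called for the response of WT and 122 list tests instead of 123 passed; the call lost was that of actin and SRF targets in the difference between the responses of C12orf49 KO and WT (adjusted p = 0.0509). Over 45 pairs of libraries with the same number, the correlation of their departures from the group means ran from -0.104 to 0.0788, and 2 of 18 libraries had their highest value with their own number.

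With 18973748 to 33211605 assigned reads per library, folds of low-count genes are the least certain: LAYN and FBXO17 had 0 to a few reads in C12orf49 KO, and COL11A1 had 5 in C12orf49 KO control. Fold changes against those groups depend on the floor or prior count.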
